A study of Mus musculus with 9 samples.

How the data were processed

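Messenger RNA was sequenced from mouse hearts in 9 libraries, 3 from each of the groups that the labels call control, DOX and TPTN. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected on oligo(dT) beads and fragmented, and strand-marked libraries were made with dUTP and sequenced as paired reads on an Illumina instrument. The animals were wild-type C57BL/6 mice of 8 to 12 weeks, per the labels.

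The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to the library's mapped fragments) for 29237 genes in each of the 9 libraries. Per the submitters' processing notes, the work used cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the mouse genome GRCm38, and these notes also name DESeq2 and edgeR, without saying which step each tool did. FPKM divides by transcript length and by the library's total, so a change in a few very abundant transcripts moves the values of all others the opposite way. The authors' deposited table also carries a p-value, a q-value and a yes or no column per gene, and its header does not say which groups were compared. In it 2892 genes are marked yes, as many as have a p-value under 0.05, and 1047 have a q-value under 0.05.

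Read counts were not used here. The most frequent low value of FPKM times transcript length, over 15203 genes with a single listed transcript, was taken as the worth of 1 read pair and gave an estimated depth per library. Only 15.8 to 18.4% of low values were whole multiples of that worth within a tolerance of 0.05, so no test of counts was made. The design, written in advance, named a count model for counts and limma where FPKM alone is held, and limma was used.

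Values were tested as log2(FPKM + 1) in genes with a mean FPKM of at least 0.5 over the 9 libraries, which left 12500 genes. A single limma 3.58.1 model (R 4.3.3, data.table version 1.17.8) held a mean per group, with empirical Bayes moderation, a mean-variance trend and robust estimation, so the 3 comparisons shared an estimate of the spread on 6 residual degrees of freedom. Genes past the threshold had a Benjamini-Hochberg adjusted p under 0.05 in limma's moderated test of either direction, with no minimum fold change. A log2 change on this scale understates the change of genes with low FPKM. A total of 51 gene lists, covering heart muscle, metabolism, stress responses, immune signalling and the cell types a heart sample could hold, was fixed before the data were examined, as were the groups, the tests, the rule for named genes and part of the other settings. Of these, 39 were tested, those with at least 3 tested members apart from a check of sample identity, with camera (preset correlation between genes of 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

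Genes named in the text follow that rule. It takes 18 genes known from doxorubicin cardiomyopathy and heart failure, and in each comparison the 5 rising and 5 falling genes with the largest log2 change among those past the threshold, with no overlap between the libraries of the groups and a group mean of at least 5 FPKM. It also takes up to 4 members with the smallest p of each list named, and up to 5 genes per direction past the threshold in both DOX against control and TPTN against DOX with opposite signs. Symbols that are only identifiers were left out. Any other gene is named as chosen after its values were seen. A gene that the rule names is not reported here.

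Positions are those of GRCm38 in the GENCODE M21 annotation, in which 29154 of the 29237 genes were found by identifier. Ribosomal protein genes, their pseudogenes, mitochondrial genes and the 7 abundant pseudogenes on chromosome 1 that copy mitochondrial genes share reads, so their single values are uncertain. Of the 31-base words in these 7 pseudogenes, 97.2 to 100% also occur in mitochondrial genes.

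The procedure was tested on simulated data, drawn as normal noise around each gene's mean with its moderated spread, in which a random set of genes was changed by 1.5, 2 and 3-fold. For DOX against control it recovered 82.1, 92.5 and 90.9% of them among 12365 genes, for TPTN against DOX 82.1, 98.5 and 93.9% among 12395 genes, and for TPTN against control 91.0, 86.6 and 93.9% among 12381 genes. False calls made up 4.46, 6.54 and 5.19% of all calls in the same order. The simulated noise was independent between genes and held no deviating library, so these shares may not carry over to the real data.

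Other settings fixed in advance were a fit of only the groups compared, no robust estimation, the replicate number as a block, a pseudocount of 0.1, no filter on low values, a minimum mean of 1 FPKM, a minimum absolute log2 change of 1, genes with a symbol only, an estimated correlation, fry, and leaving out each library in turn. Tables were also read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Scaling by median ratios, to the FPKM sum without mitochondrial genes, to that sum without their nuclear copies as well, quantile normalization, removal of the trend on length and GC content, and leaving out control replicate 3 and TPTN replicate 1 together were added after the data were seen.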

Results

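Gene expression was measured in hearts of wild-type C57BL/6 mice from 3 groups of 3 libraries each, which the labels call control, DOX and TPTN. The design text names a normal group, a doxorubicin model group and a TPTN treated group. Doxorubicin is an anthracycline used against cancer that can damage heart muscle. The labels do not say whether the TPTN mice also received doxorubicin, nor what dose or day was used. Beyond the numbers in the labels, nothing states that replicates are separate animals, so p-values measure only the spread between these samples. Estimated depth was 22.9, 24.3 and 23.8 M read pairs in control replicates 1, 2 and 3. It was 19.0, 19.1 and 18.3 M in DOX and 20.3, 21.2 and 19.2 M in TPTN. These depths are rough, as only 15.8 to 18.4% of low values were whole multiples of the estimated worth of 1 read pair.

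Mitochondrial transcripts made up the largest part of every library, with 49.8, 50.9 and 50.4% of the FPKM sum in the control replicates, 46.2, 46.0 and 44.7% in DOX and 48.3, 48.7 and 48.1% in TPTN. The 7 nuclear copies of mitochondrial genes took a further 18 to 19.7%. An abundant transcript related to 18S ribosomal RNA stood at 1086, 2403 and 1227 FPKM in control, 3370, 4018 and 5722 in DOX and 2906, 1348 and 3668 in TPTN. Small nuclear, nucleolar and Cajal body RNA and RNA annotated as miscellaneous summed to 943 FPKM in TPTN replicate 1 and 657 in control replicate 3. The sum was 139 to 447 in the other 7 libraries.

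The comparison of DOX with control asks what the doxorubicin model changed in the heart. Ribosomal protein genes were higher in DOX: their summed FPKM was 5979, 6349 and 6326 in the DOX libraries and 5058, 4426 and 4825 in the control libraries. Nr4a1, an immediate early gene that encodes a nuclear receptor, rose from 2.19 ± 0.888 FPKM to 7.38 ± 0.492 (SD, n = 3 each; log2 change 1.43, SE 0.16, limma adjusted p = 0.015). The nuclear long noncoding RNA Neat1 fell from 40.8 ± 5.87 to 22.8 ± 2.02 FPKM (log2 change -0.81, SE 0.11, adjusted p = 0.015). Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 from 101254269 to 101274795 and Neat1 (ENSMUSG00000092274) on chromosome 19 from 5824708 to 5845478.

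Among the other genes with the largest changes, Hes1, a transcription factor downstream of Notch, rose by 0.76 on the log2 scale (2.67 ± 0.285 to 5.27 ± 1.07 FPKM), and the small GTPase gene Arl4d by 0.75. The ribosomal protein gene Rpl7a rose by 0.95 and the pseudogene Rpl38-ps2 by 0.72. Scn4b, a sodium channel subunit gene, fell by 0.76 (7.99 ± 1.04 to 4.39 ± 1.19 FPKM, adjusted p = 0.0405). Thrsp, a gene of fatty acid synthesis, fell by 0.64 (adjusted p = 0.0449), and the mitochondrial transfer RNA gene mt-Th by 1.41 (adjusted p = 0.0452). None of the 16 tested genes fixed for doxorubicin cardiomyopathy and heart failure passed the threshold. Nppa, the atrial natriuretic peptide gene, was at 97.5 ± 48.2 FPKM in control and 740 ± 864 in DOX (log2 change 2.36, SE 0.91, adjusted p = 0.25). Nppb had a log2 change of 0.53 (adjusted p = 0.732), Myh7 of 0.14 (adjusted p = 0.436), Acta1 of -0.85 (adjusted p = 0.339) and Atp2a2 of -0.16 (adjusted p = 0.237). Gdf15 and Top2a lay below the expression minimum.

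Of the 39 gene lists tested, 6 passed the threshold, 4 higher and 2 lower in DOX relative to the other genes. Camera compares the members of a list with the other genes tested, so its direction is not one against the other group alone. Ribosomal proteins had 22 of 34 genes higher and 0 lower, or 32 higher adjusted over the list alone, with a median log2 change of 0.38 (camera adjusted p = 3.55e-24, and adjusted p = 0.402 with an estimated correlation). Rps19 rose by 0.61 (14.7 ± 0.614 to 23 ± 1.03 FPKM), Rpl3 by 0.69, Rpl13a by 0.60 and Rps15 by 0.59. Mitochondrially encoded genes had 5 of 13 lower, or 11 adjusted over the list alone. The median was -0.23 (adjusted p = 3.53e-12, and adjusted p = 0.402 with an estimated correlation), among them mt-Nd4l at -0.40, mt-Co1 at -0.36 and mt-Nd5 at -0.35. Under quantile normalization, in which the most abundant genes are set to equal values, the median of this list was 0.00. Nuclear respiratory chain genes had 4 of 38 higher, or 16 adjusted over the list alone. The median was 0.17 (adjusted p = 2.12e-05, and adjusted p = 0.881 with an estimated correlation). It was 0.10 under median ratios, 0.02 under quantile normalization and 0.000977 when scaled to the sum without mitochondrial genes and their nuclear copies. In that last scaling the ribosomal protein median was 0.22 and the mitochondrially encoded one -0.39, and under quantile normalization the ribosomal protein median was 0.24. The 4 were Ndufb8 at 0.46, Ndufb10 at 0.41, Atp5o at 0.40 and Cox6a2 at 0.30.

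Glycolysis genes had 3 of 22 higher, or 10 higher and 1 lower adjusted over the list alone. The median was 0.18 (adjusted p = 0.0138, and adjusted p = 0.881 with an estimated correlation). It was 0.11 under median ratios, 0.02 under quantile normalization and 0.01 when scaled without mitochondrial genes and their copies. The 3 were Tpi1 at 0.38, Eno3 at 0.36 and Eno1 at 0.31. Immediate early genes had Nr4a1 alone of 20 past the threshold, or 4 adjusted over the list alone. The median was 0.30, or 0.18 without control replicate 2 (adjusted p = 0.0028 with all libraries, and adjusted p = 0.881 with an estimated correlation). Acute phase and glucocorticoid-responsive genes had 2 of 20 lower, Fam107a at -0.57 and Fkbp5 at -0.48, or 5 adjusted over the list alone. The median was -0.15 (adjusted p = 7.66e-05, and adjusted p = 0.402 with an estimated correlation). It was -0.05 without control replicate 2, -0.22 without control replicate 3 (with or without TPTN replicate 1) and -0.28 when scaled without mitochondrial genes and their copies, where the immediate early median was 0.19. Sarcomere genes did not pass (2 of 22 higher, adjusted p = 0.0691), with a median of 0.16 that was -0.0032 without mitochondrial genes and their copies in the sum and -0.01 under quantile normalization. They passed without DOX replicate 1 (median 0.20, adjusted p = 0.00824), with the trend on length and GC content removed (0.15, adjusted p = 0.0241) and in fry (adjusted p = 0.0229). Calcium handling genes passed as lower without DOX replicate 1 (median -0.08, adjusted p = 0.0165, against 0.117 with it). The p53 targets did not pass (adjusted p = 0.726), although 2 of their 23 tested members, Phlda3 at 0.58 and Ephx1 at 0.44, rose. Atrial cardiomyocyte markers had a median of 1.9 with 0 of 11 past the threshold in limma (adjusted p = 0.0545). Without DOX replicate 1 the median was 0.12 (adjusted p = 0.15). The list passed under median ratios (adjusted p = 0.00788), quantile normalization (0.0047), scaling without mitochondrial genes alone (0.021) and scaling without their copies as well (8.6e-05).

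In all, 279 genes were higher and 50 lower in DOX than in control (84.8% higher), and 2256 had an unadjusted p under 0.05. The split of calls depended on the scaling: scaling by median ratios gave 118 higher and 64 lower (64.8%), quantile normalization gave 76 and 67 (53.1%), and scaling to the sum without mitochondrial genes and their nuclear copies gave 61 and 209 (22.6%). That last scaling moved the median of all genes from 0.04 to -0.07; relative to the all-gene median, ribosomal proteins stood at 0.29 in place of 0.33 and respiratory chain genes at 0.07 in place of 0.12. The calls of respiratory chain genes (adjusted p = 0.0927) and glycolysis (adjusted p = 0.15) were lost there. Leaving out single libraries changed the counts of higher and lower genes to 2 and 0 without control replicate 2, 4 and 0 without control replicate 3, 5 and 2 without DOX replicate 2, 74 and 17 without DOX replicate 3, 173 and 32 without control replicate 1 and 172 and 32 without TPTN replicate 3. At an unadjusted p under 0.05, limma still gave 1350 higher and 405 lower genes without control replicate 2. Without control replicate 3 it gave 1457 and 331, and with all libraries 1822 and 434. Fits that leave out a library also hold fewer samples. The naming rule, with list members only from lists that passed, gave 34 genes past the threshold in limma. Of these, 0 passed in all 9 such fits and 0 changed sign. Other genes named for this comparison, such as Phlda3 and Ephx1, were not part of this tally. The number lost was 33 without control replicate 2, 33 without control replicate 3, 31 without DOX replicate 2, 15 without DOX replicate 3, 9 without control replicate 1, 6 without TPTN replicate 3, 5 without TPTN replicate 2, 4 without DOX replicate 1 and 3 without TPTN replicate 1. The glycolysis list was lost without DOX replicate 3 (adjusted p = 0.0827), under quantile normalization (adjusted p = 0.465) and with the trend on length and GC content removed (adjusted p = 0.0515). Quantile normalization also ended the calls of respiratory chain genes (adjusted p = 0.551) and mitochondrially encoded genes (adjusted p = 0.814).

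**Figure D1:**
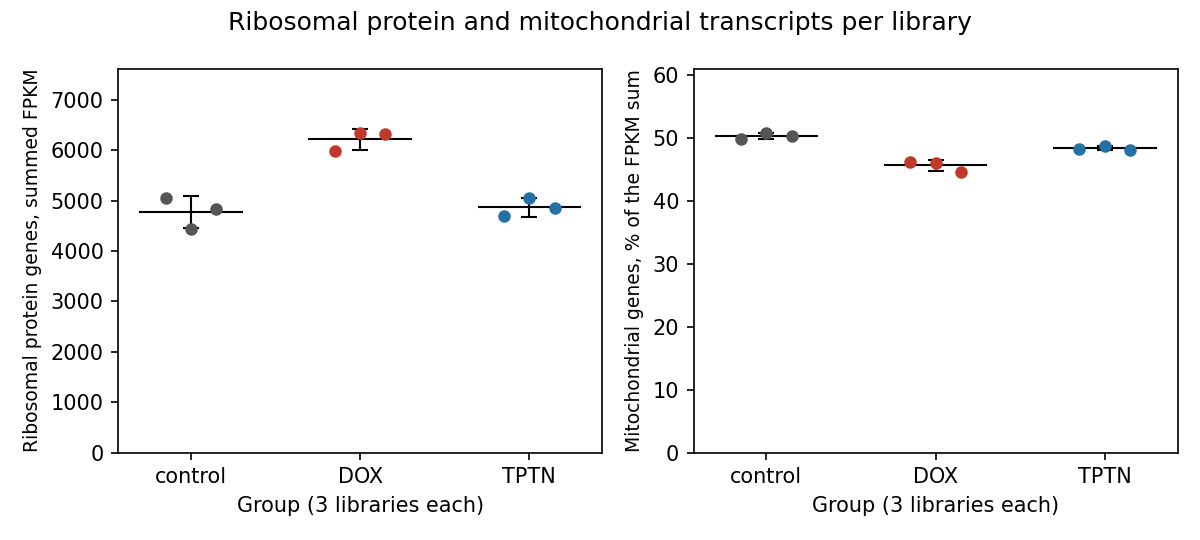
Summed FPKM of ribosomal protein genes (left) and mitochondrial transcripts as a percent of the FPKM sum (right) in each library of the control, DOX and TPTN groups, with lines at the group means and bars of 1 SD. The DOX libraries lie at 5979 to 6349 FPKM on the left, above the 6 others at 4426 to 5058, and at 44.7 to 46.2% on the right, below the 6 others at 48.1 to 50.9%.

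The comparison of TPTN with DOX asks how the treated group differed from the model group. As the labels do not say whether the TPTN mice received doxorubicin, it may hold more than the treatment. Sult1a1, a sulfotransferase gene, fell from 19.9 ± 0.878 FPKM in DOX to 6.53 ± 0.346 in TPTN (SD, n = 3 each; log2 change -1.47, SE 0.09, limma adjusted p = 0.000101). Adh1, an alcohol dehydrogenase gene, fell from 6.07 ± 1.3 to 1.49 ± 0.416 FPKM (log2 change -1.50, SE 0.15, adjusted p = 0.00759). The gene of the apelin receptor, Aplnr, rose from 4.84 ± 0.88 to 12 ± 2.17 FPKM (log2 change 1.15, SE 0.14, adjusted p = 0.0085), and that of its ligand, Apln, from 2.73 ± 0.436 to 6.09 ± 1.26 (log2 change 0.92). Ribosomal protein genes were lower in TPTN, at a summed FPKM of 4687, 5057 and 4849. Sult1a1 (ENSMUSG00000030711) lies on chromosome 7 from 126672865 to 126676432, Adh1 (ENSMUSG00000074207) on chromosome 3 from 138260991 to 138290698, Aplnr (ENSMUSG00000044338) on chromosome 2 from 85136225 to 85139923 and Apln (ENSMUSG00000037010) on chromosome X from 48025146 to 48034853.

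Other large rises were those of cyclin D1, Ccnd1 (6.88 ± 1.43 to 14.9 ± 0.676 FPKM, log2 change 1.03), the intermediate filament gene Nes (0.81) and the collagen gene Col15a1 (0.75). Large falls included Timp4, an inhibitor of matrix metalloproteinases (7.62 ± 2.27 to 2.71 ± 0.123 FPKM, log2 change -1.18), the clock gene Per1 (-1.15) and Cdkn1a, which encodes the cell cycle inhibitor p21 (13.2 ± 2.36 to 6.15 ± 0.675 FPKM, log2 change -0.98, adjusted p = 0.0254). Of the genes fixed for cardiomyopathy, Cdkn1a and Col3a1 passed, Col3a1 with a rise of 0.65 (11.5 ± 1.83 to 18.5 ± 1.66 FPKM, adjusted p = 0.0282).

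Of the 39 lists, 11 passed, 5 higher and 6 lower in TPTN relative to the other genes, and 0 of them passed with an estimated correlation. Ribosomal proteins had 27 of 34 genes lower, or 32 adjusted over the list alone. The median was -0.35 (camera adjusted p = 1.31e-22, and adjusted p = 0.482 with an estimated correlation). Nuclear respiratory chain genes had 6 of 38 lower, or 25 adjusted over the list alone. The median was -0.20 (adjusted p = 1.48e-11, and adjusted p = 0.784 with an estimated correlation). It was -0.07 when scaled to the sum without mitochondrial genes and their copies and -0.04 under quantile normalization, where the ribosomal protein median was -0.21 in both. Acute phase and glucocorticoid-responsive genes had 9 of 20 lower, or 13 adjusted over the list alone. The median was -0.54 (adjusted p = 4.06e-09, and adjusted p = 0.293 with an estimated correlation). Sult1a1, Per1, Cdkn1a and the FK506 binding protein gene Fkbp5 (-0.71) were among the 9. Extracellular matrix genes had 9 of 33 higher, or 14 higher and 2 lower adjusted over the list alone. The median was 0.35 (adjusted p = 1.3e-06, and adjusted p = 0.784 with an estimated correlation), or 0.19 without DOX replicate 3 and 0.20 with no filter on low values. They included Col15a1, Col3a1, Col4a2 at 0.62 and Col6a3 at 0.52.

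Cell cycle genes had only Ccnd1 of 13 past the threshold, or 4 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.00325, and adjusted p = 0.482 with an estimated correlation). Interferon-stimulated genes had 0 of 33 past the threshold in limma, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05, with a median of 0.19 (adjusted p = 4.64e-05, and adjusted p = 0.784 with an estimated correlation). It was 0.30 without DOX replicate 2, 0.31 without TPTN replicate 1, 0.13 without TPTN replicate 2 0.31 without control replicate 3 and TPTN replicate 1 together and 0.31 with a pseudocount of 0.1. That pseudocount gave 0.31 for cell cycle and no filter gave 0.09. Heat shock genes had Hspd1 higher at 0.37 of 18, or 2 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.00977, and adjusted p = 0.784 with an estimated correlation). It was 0.29 without mitochondrial genes and their copies in the sum and 0.29 under quantile normalization. Fatty acid oxidation genes had 1 of 26 lower, Acaa2 at -0.33, or 5 adjusted over the list alone. Their median was -0.12 (adjusted p = 0.00863, and adjusted p = 0.784 with an estimated correlation), but 0.01 when scaled to the sum without mitochondrial genes and their nuclear copies and 0.04 under quantile normalization. Autophagy and lysosome genes had 2 of 23 lower, Map1lc3a at -0.38 and Map1lc3b at -0.30, or 1 higher and 6 lower adjusted over the list alone. Their median was -0.12 (adjusted p = 0.0395, and adjusted p = 0.784 with an estimated correlation), but 0.01 without mitochondrial genes and their copies in the sum. It was -0.07 without DOX replicate 1 and under quantile normalization. Scaled without mitochondrial genes alone, the fatty acid oxidation and autophagy medians were each -0.06.

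Mitochondrially encoded genes had 0 of 13 past the threshold in limma, 3 higher adjusted over the list alone and 4 at an unadjusted p under 0.05, with a median of 0.06 (adjusted p = 0.0395, and adjusted p = 0.784 with an estimated correlation) that was 0.00 under quantile normalization. It was 0.03 without DOX replicate 1, 0.10 without DOX replicate 2 and 0.03 without TPTN replicate 2. It was 0.13 without mitochondrial genes alone in the sum, 0.20 without their copies as well and 0.13 with the trend on length and GC content removed. Atrial markers had 0 of 11 past the threshold in limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, with a median of -1.85 (adjusted p = 0.00863, and adjusted p = 0.784 with an estimated correlation). Without DOX replicate 1 the atrial median was -0.14 and the call was lost (adjusted p = 0.0528). In that fit sarcomere genes (median -0.15, 4 lower), calcium handling genes (0.16) and erythrocyte markers (-0.74) passed, each with adjusted p = 0.0156. With all libraries their medians were -0.09, 0.08 and -0.24 and they did not pass (adjusted p = 0.0823, 0.0762 and 0.531). The p53 targets did not pass as a list (adjusted p = 0.244), while 4 of 23 fell, or 1 higher and 6 lower adjusted over the list alone: Cdkn1a, Sesn1 at -0.55, Fas at -0.48 and Ephx1 at -0.32.

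In all, 99 genes were higher and 308 lower in TPTN than in DOX (24.3% higher), and 2581 had an unadjusted p under 0.05. Median ratios gave 151 higher and 288 lower (34.4%), quantile normalization 173 and 163 (51.5%), scaling without mitochondrial genes alone 187 and 170 (52.4%), and scaling without these and their nuclear copies 542 and 129 (80.8%). Without DOX replicate 2 the counts were 22 higher and 52 lower, without DOX replicate 3 12 and 48, without TPTN replicate 1 19 and 31, without TPTN replicate 2 14 and 72, without TPTN replicate 3 9 and 36, without control replicate 3 58 and 154, and without DOX replicate 1 162 and 306. The naming rule, with list members only from lists that passed, gave 34 genes past the threshold. Of these, 9 passed in all 9 such fits: Aplnr, Adh1, Sult1a1, Per1, Rps19, Rpl13a, Fau, Rps16 and Smim5. Sesn1, Fas and Ephx1, named above, were not part of this tally. The number lost was 25 without TPTN replicate 3, 23 without TPTN replicate 1, 21 without TPTN replicate 2, 21 without DOX replicate 3, 16 without DOX replicate 2, 8 without control replicate 3 and 5 without DOX replicate 1. Quantile normalization ended the calls of fatty acid oxidation (adjusted p = 0.49), respiratory chain (0.0782), mitochondrially encoded (0.96) and autophagy genes (0.397). Scaling without mitochondrial genes and their copies ended those of fatty acid oxidation (0.289) and autophagy (0.144), as did scaling without mitochondrial genes alone (0.0563 and 0.0717), and median ratios ended that of autophagy (0.0565). A pseudocount of 0.1 ended those of mitochondrially encoded genes (0.0699) and autophagy (0.0504), and a minimum mean of 1 FPKM these (0.0503 and 0.0572) and cell cycle (0.0696). The mitochondrially encoded call was also lost with only the groups compared (0.0503) and with symbols only (0.054). Without control replicate 3 and TPTN replicate 1 together, fatty acid oxidation (0.0636), mitochondrially encoded genes (0.0854) and autophagy (0.145) were lost. Lists also lost their calls when 1 library was left out, here with the adjusted p. Without DOX replicate 1 these were mitochondrially encoded genes (0.135), heat shock (0.135), interferon (0.0528), autophagy (0.0528) and atrial markers (0.0528). Without DOX replicate 3 they were fatty acid oxidation (0.0608), mitochondrially encoded genes (0.085) and autophagy (0.135). Without TPTN replicate 1 they were heat shock (0.0507), mitochondrially encoded genes (0.0792) and autophagy (0.139). Without TPTN replicate 2 they were fatty acid oxidation (0.0546) and mitochondrially encoded genes (0.0884), and without TPTN replicate 3 autophagy (0.0595).

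The comparison of TPTN with control asks how far the TPTN group lay from the normal group. Glucocorticoid-responsive genes were lower in TPTN: Fkbp5 fell from 3.56 ± 0.784 FPKM to 0.982 ± 0.0472 (SD, n = 3 each; log2 change -1.19, SE 0.11, limma adjusted p = 0.00192) and the transcription factor gene Klf15 from 11.9 ± 0.899 to 5.97 ± 0.601 (log2 change -0.88, SE 0.11, adjusted p = 0.00819). Sult1a1 fell by 1.23 on the log2 scale (16.7 ± 2.3 to 6.53 ± 0.346 FPKM, adjusted p = 0.000647) and Adh1 by 1.52 (adjusted p = 0.00383). Nr1d1, which encodes the clock repressor REV-ERB alpha, rose from 7.19 ± 0.431 to 16.3 ± 2.95 FPKM (log2 change 1.07, SE 0.13, adjusted p = 0.00969). Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527, Klf15 (ENSMUSG00000030087) on chromosome 6 from 90462576 to 90475238 and Nr1d1 (ENSMUSG00000020889) on chromosome 11 from 98767932 to 98775333.

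The other genes with the largest changes were Aplnr at 1.02, Ccnd1 at 0.97, Inka2 at 0.96 (4.19 ± 1.09 to 8.99 ± 1.13 FPKM) and Apln at 0.93, and, lower in TPTN, Timp4 at -1.34 and Cdkn1a at -1.08. Col3a1 rose by 0.74 (adjusted p = 0.0285). The p53 targets did not pass as a list (median -0.0025, adjusted p = 0.639). Of 23 tested, 3 fell, Cdkn1a, Sesn1 by 0.62 and Fas by 0.60, or 1 higher and 3 lower adjusted over the list alone.

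**Figure D2:**
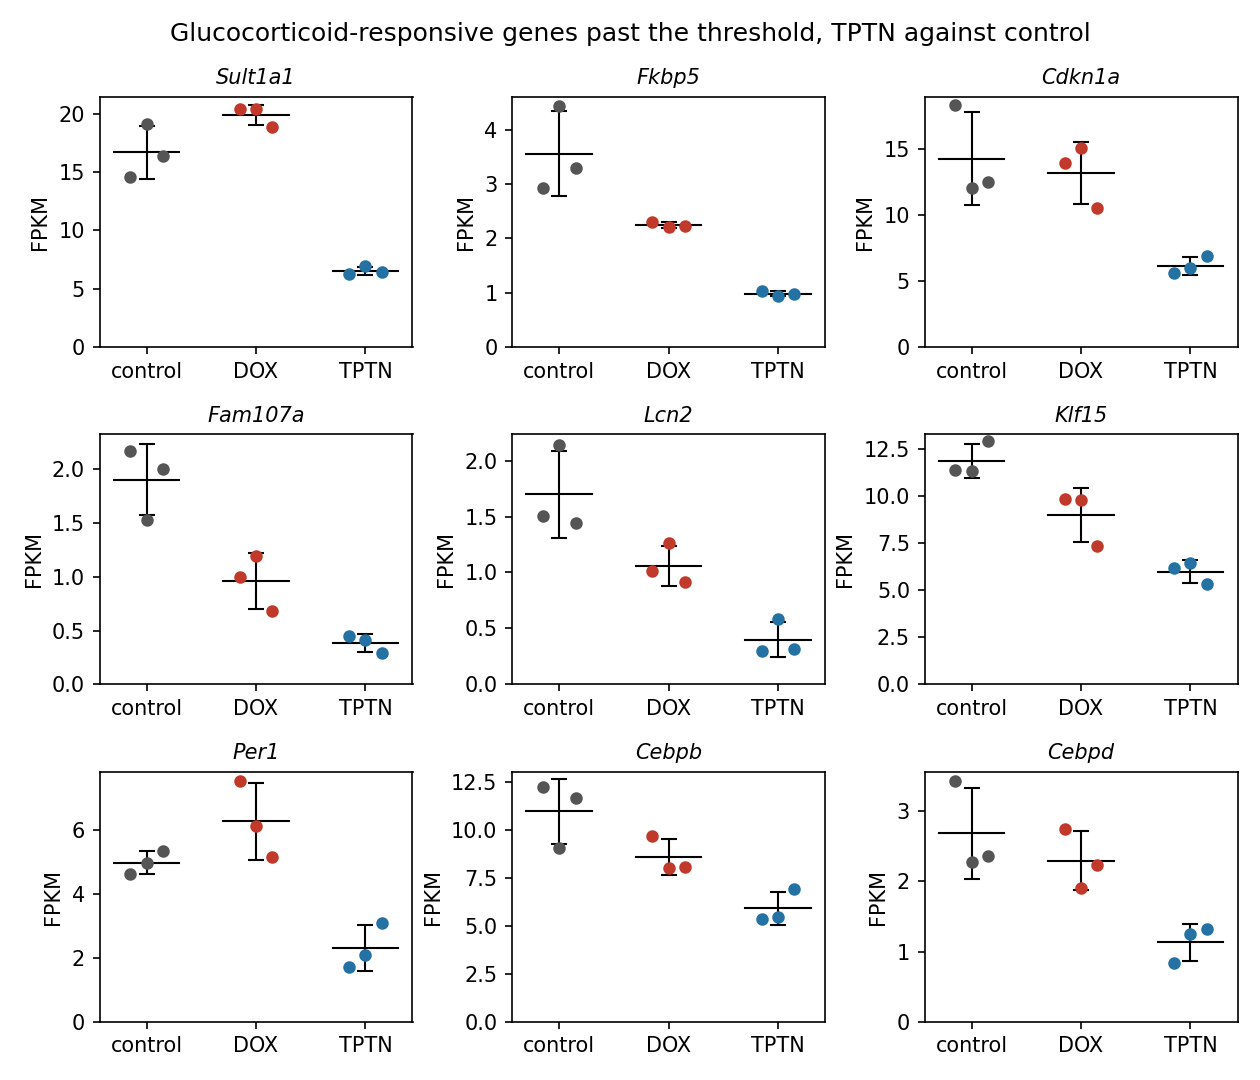
FPKM of 9 genes of the acute phase and glucocorticoid-responsive list in the control, DOX and TPTN libraries, with points for libraries, lines at the group means and bars of 1 SD. Fkbp5 averages 3.56 FPKM in control, 2.25 in DOX and 0.982 in TPTN, and Klf15 averages 11.9, 8.98 and 5.97.

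Of the 39 lists, 14 passed, 5 higher and 9 lower in TPTN relative to the other genes. The median log2 change of all genes was 0.04, so a list with a median near 0 can pass as lower. Acute phase and glucocorticoid-responsive genes had 9 of 20 lower, or 16 adjusted over the list alone, with a median of -0.88 (camera adjusted p = 1.47e-26). This was the only list call of the 3 comparisons that held with an estimated correlation (adjusted p = 0.0175). Among the 9 were Sult1a1, Fkbp5, Cdkn1a, Klf15, Per1 at -0.88 and Fam107a at -1.06. Cell cycle genes had 2 of 13 higher, Ccnd1 and the replication gene Mcm3 at 0.41, or 7 adjusted over the list alone, with a median of 0.21 (adjusted p = 1.07e-05, and adjusted p = 0.196 with an estimated correlation). Extracellular matrix genes had 2 of 33 higher, Col15a1 at 0.78 and Col3a1, or 14 adjusted over the list alone, with a median of 0.23 (adjusted p = 2.19e-06, and adjusted p = 0.74 with an estimated correlation).

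The remaining 11 lists that passed had 0 members past the threshold in limma. Mitochondrially encoded genes had a median of -0.15 that was 0.00 under quantile normalization, 7 of 13 lower adjusted over the list alone and 8 at an unadjusted p under 0.05 (adjusted p = 2.53e-08, and adjusted p = 0.299 with an estimated correlation). Fatty acid oxidation genes had a median of -0.11, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 2.08e-06, and adjusted p = 0.74 with an estimated correlation). PPAR-responsive genes had a median of -0.14, 2 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.000125, and adjusted p = 0.74 with an estimated correlation). Nuclear respiratory chain genes had a median of -0.05, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (adjusted p = 0.000886, and adjusted p = 0.837 with an estimated correlation). The tricarboxylic acid cycle had a median of -0.04, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (adjusted p = 0.022, and adjusted p = 0.837 with an estimated correlation). Glycolysis genes had a median of 0.11, 2 higher adjusted over the list alone and 7 at an unadjusted p under 0.05 (adjusted p = 0.0385, and adjusted p = 0.837 with an estimated correlation). Leaving out 1 library moved these medians by over 1.5 times in some fits. Without TPTN replicate 1 the median was -0.06 for fatty acid oxidation, -0.02 for the respiratory chain and -0.02 for the tricarboxylic acid cycle. Without TPTN replicate 2 it was -0.08 for the respiratory chain and -0.06 for the tricarboxylic acid cycle. Without control replicate 1 it was -0.03 for the respiratory chain, without control replicate 2 -0.08 for PPAR-responsive genes and 0.06 for glycolysis, and without control replicate 3 -0.38 for PPAR-responsive genes.

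Interferon-stimulated genes had a median of 0.19, 0 adjusted over the list alone and 3 higher and 1 lower at an unadjusted p under 0.05 (limma), with adjusted p = 0.0213, and adjusted p = 0.867 with an estimated correlation. Smooth muscle and pericyte markers had a median of 0.19, 2 higher adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.0213, and adjusted p = 0.74 with an estimated correlation). Muscle atrophy genes had a median of -0.14, 2 lower adjusted over the list alone and 1 higher and 7 lower at an unadjusted p under 0.05 (adjusted p = 0.022, and adjusted p = 0.74 with an estimated correlation). Autophagy genes had a median of -0.02 that was 0.01 when scaled without mitochondrial genes alone, with 3 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.0348, and adjusted p = 0.837 with an estimated correlation). NRF2 and antioxidant genes had a median of -0.02 that was also 0.01 in that scaling, with 2 lower adjusted over the list alone and 1 higher and 4 lower at an unadjusted p under 0.05 (adjusted p = 0.0418, and adjusted p = 0.837 with an estimated correlation). Over the other settings that moved medians by over 1.5 times, the respiratory chain ranged from -0.10 to -0.0087, the tricarboxylic acid cycle from -0.09 to -0.0059, glycolysis from 0.06 to 0.17, NRF2 from -0.07 to 0.02 and autophagy from -0.07 to 0.05. Mitochondrially encoded genes were at -0.08 with the trend on length and GC content removed, and cell cycle at 0.43 with a pseudocount of 0.1 and 0.12 with no filter, where muscle atrophy was at -0.08. Without control replicate 3 and TPTN replicate 1 together the median was 0.43 for interferon, -0.37 for PPAR-responsive genes, 0.28 for smooth muscle, -0.07 for fatty acid oxidation and -0.09 for muscle atrophy. Single libraries also moved medians here by over 1.5 times. Without TPTN replicate 1 the median was 0.32 for interferon, 0.02 for NRF2 and 0.04 for autophagy. Without TPTN replicate 2 it was 0.11 for smooth muscle, -0.06 for NRF2 and -0.07 for autophagy, and without TPTN replicate 3 0.10 for interferon, -0.04 for NRF2 and -0.05 for autophagy. For muscle atrophy it was 0.01, -0.07 and -0.07 without control replicates 1, 2 and 3 in turn. For autophagy it was 0.00226 without control replicate 1 and -0.05 without control replicate 2, where NRF2 was at -0.03. Ribosomal proteins did not pass (0 of 34 in limma and 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, adjusted p = 0.936). Their median was 0.03; over the 89 genes of the whole family it was also 0.03, and -0.03 under median ratios and -0.01 without mitochondrial genes and their copies in the sum. In 10, 6 and 9 of the 39 lists, in DOX against control, TPTN against DOX and TPTN against control in turn, the median, the mean and the test differed in sign, and none of those lists passed.

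**Figure D3:**
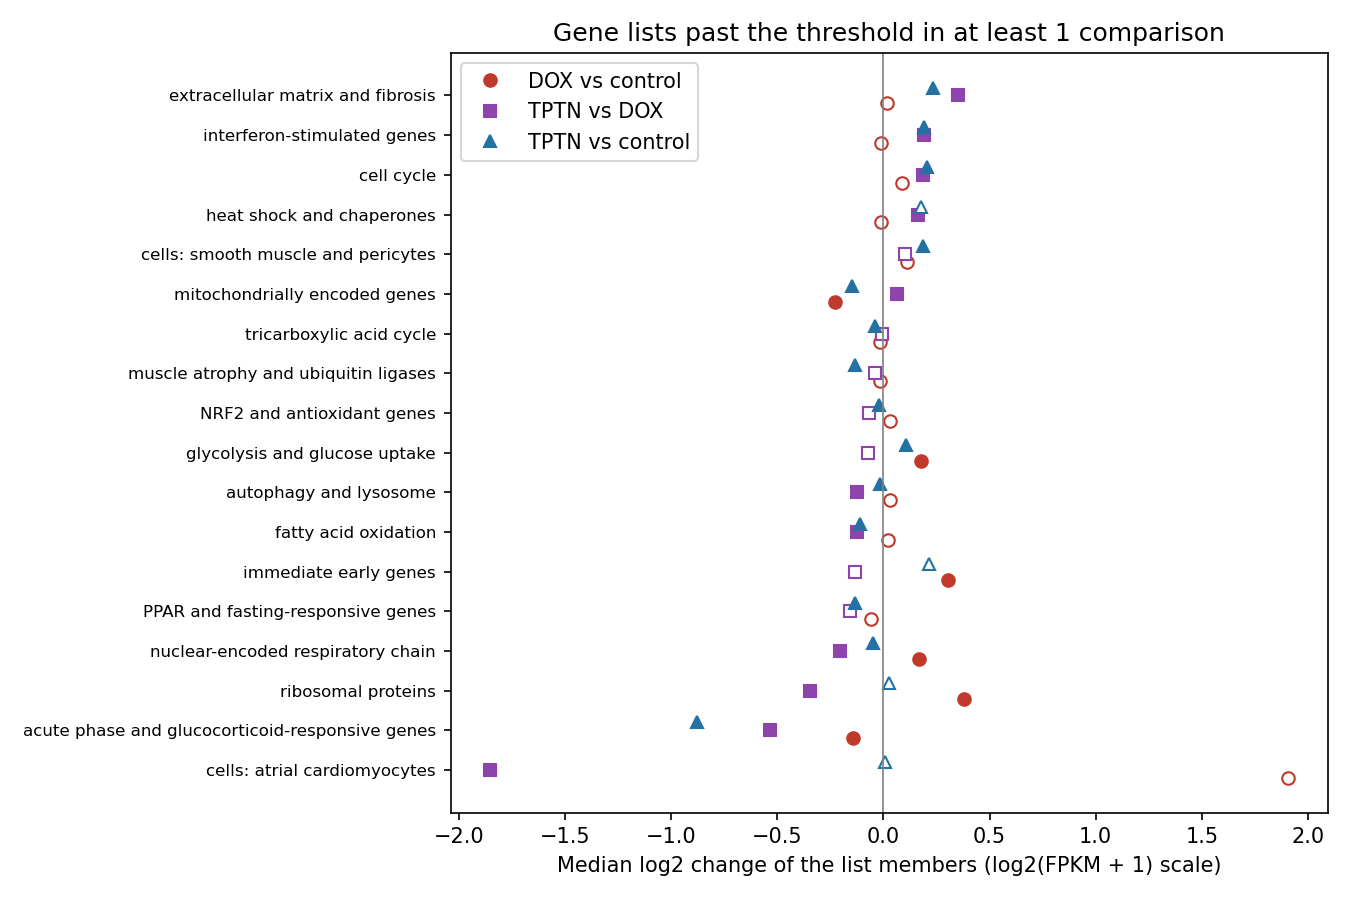
Median log2 change of gene lists (horizontal axis, log2 scale) for DOX against control (circles), TPTN against DOX (squares) and TPTN against control (triangles), filled where the camera adjusted p was under 0.05 and open elsewhere. Ribosomal proteins lie at 0.38 and -0.35 in the first comparisons, with the sign kept in the 4 other scalings, and glucocorticoid-responsive genes at -0.15, -0.54 and -0.88, while fatty acid oxidation genes at -0.12 in TPTN against DOX lie at 0.04 under quantile normalization and 0.01 without mitochondrial genes and their copies in the sum.

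In all, 42 genes were higher and 48 lower in TPTN than in control (46.7% higher), and 1642 had an unadjusted p under 0.05. Scaling without mitochondrial genes alone gave 90 higher and 55 lower (62.1%). Without control replicate 1 the counts were 85 higher and 63 lower, without control replicate 2 13 and 20, without control replicate 3 13 and 21, without DOX replicate 1 61 and 74, without TPTN replicate 1 20 and 14, without TPTN replicate 2 9 and 20, and without TPTN replicate 3 4 and 17. The naming rule, with list members only from lists that passed, gave 15 genes past the threshold here. Of these, 6 passed in all 9 such fits: Nr1d1, Adh1, Sult1a1, Klf15, Fkbp5 and Fam107a. Other genes named for this comparison, such as Per1, Sesn1 and Fas, were not part of this tally. The number lost was 9 without TPTN replicate 3, 8 without TPTN replicate 2, 8 without control replicate 2, 7 without TPTN replicate 1, 6 without control replicate 3, 3 without DOX replicate 3 and 1 without DOX replicate 2. Quantile normalization ended the calls of respiratory chain (adjusted p = 0.113), mitochondrially encoded (0.959), tricarboxylic acid cycle (0.238), NRF2 (0.105), autophagy (0.105) and muscle atrophy genes (0.0943). Median ratios ended that of glycolysis (0.092), as did scaling without mitochondrial genes and their copies (0.05), a fit of only the groups compared (0.0606), the replicate block (0.055) and a pseudocount of 0.1 (0.0705). Removal of the trend on length and GC content ended those of smooth muscle markers (0.0592), the tricarboxylic acid cycle (0.0591) and NRF2 (0.0832). Scaling without mitochondrial genes alone ended those of the tricarboxylic acid cycle (0.0922), NRF2 (0.0722) and autophagy (0.0722). A pseudocount of 0.1 also ended that of NRF2 (0.0639), and no filter on low values those of NRF2 (0.219), muscle atrophy (0.166) and autophagy (0.0786). Without control replicate 3 and TPTN replicate 1 together, respiratory chain genes (0.124), the tricarboxylic acid cycle (0.195), NRF2 (0.14, median 0.02) and autophagy (0.4, median 0.05) were lost. Lists also lost their calls when 1 library was left out, here with the adjusted p. Without control replicate 2 these were PPAR-responsive genes (0.178), the tricarboxylic acid cycle (0.0672), glycolysis (0.186), NRF2 (0.234), interferon (0.186), muscle atrophy (0.169), autophagy (0.0801) and smooth muscle (0.167). Without control replicate 1 they were glycolysis (0.0947) and interferon (0.158), and without control replicate 3 the tricarboxylic acid cycle (0.052) and autophagy (0.0982). Without TPTN replicate 1 they were the tricarboxylic acid cycle (0.133), NRF2 (0.201) and autophagy (0.267). Without TPTN replicate 2 they were glycolysis (0.0727), interferon (0.147), muscle atrophy (0.146) and smooth muscle (0.134). Without TPTN replicate 3 they were glycolysis (0.109) and interferon (0.27), and without DOX replicate 3 glycolysis (0.0531). Medians changed sign for NRF2 without TPTN replicate 1 (0.02), for muscle atrophy without control replicate 1 (0.01) and for autophagy without control replicate 1 (0.00226) and TPTN replicate 1 (0.04).

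Genes past the threshold in both DOX against control and TPTN against DOX mostly had opposite signs: 133 rose in DOX and fell in TPTN, 11 fell in DOX and rose in TPTN, and 3 had the same sign. The balance of directions turned with the scaling: these counts were 30 and 86 without mitochondrial genes and their nuclear copies in the sum, 32 and 30 under quantile normalization, 79 and 28 without mitochondrial genes alone and 76 and 15 under median ratios, with 2 of the same sign in each. These 144 genes included 34 ribosomal protein genes, 8 of their pseudogenes and 1 mitochondrial gene, and 0 of them passed in TPTN against control. They were picked for DOX libraries that lie apart from both other groups in 1 direction. That choice favours TPTN values near control, so the 0 is no separate sign of a return. Rps19 went from 14.7 FPKM in control to 23 in DOX and 16.4 in TPTN, and Smim5, a small membrane protein gene, from 3.71 to 5.88 and 3.45. In the other direction the matrix gene Hmcn2 went from 1.75 to 0.85 and 1.73, the cell adhesion gene Ceacam1 from 1.91 to 1.05 and 1.91, and the Golgi gene Golga4 from 24.4 to 17.3 and 22. Both comparisons use the DOX libraries, so opposite signs arise by chance. In 50 simulations with no effect, 0 such genes were called on average. Noise alone passes the threshold in almost no gene, so that count was set in advance and is no baseline for the 144. Independent lists would share 6.87 and 0.396, a value that leaves out the sharing of the DOX libraries. The covariance of the log2 changes was -0.0271 against -0.0109 simulated, and the correlation across genes, which are not independent replicates, -0.64 against -0.50. The DOX libraries are too few to be split, so how many of the 144 calls come from their sharing is not known. The number of opposite calls was 2 without control replicate 2, 3 without control replicate 3, 6 without DOX replicate 2 and 22 without DOX replicate 3. It was 17 without TPTN replicate 1, 39 without TPTN replicate 2 and 17 without TPTN replicate 3. It was 91 under median ratios, 62 under quantile normalization, 29 with the trend on length and GC content removed, 52 with the replicate block, 68 in fits of only the groups compared and 1 with no filter on low values.

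Both DOX and TPTN differed from control in the same direction in 23 genes, 15 higher and 8 lower, and in opposite directions in 0. In 50 simulations with no effect, 0.02 same-direction genes were called on average, and independent lists would share 0.937 and 0.192. Noise alone calls almost no genes and independent lists leave out the shared controls, so neither is a baseline for the 23. Among the 23 genes, Neat1 had log2 changes of -0.81 and -0.70, Fkbp5 of -0.48 and -1.19, Fam107a of -0.57 and -1.06 and Nr1d1 of 0.64 and 1.07. The covariance was 0.0133 against 0.0110 simulated, and the correlation across genes 0.38 against 0.51. Over all genes, 62.1% had the same sign against 66.6% simulated. This share and the correlation both lay below the value that shared controls alone give in simulation. The control libraries are too few to be split, so how many of the 23 calls come from their sharing is not known. The number of same-direction calls was 0 without control replicate 2, 0 without control replicate 3, 1 without DOX replicate 2 and 6 without DOX replicate 3. It was 10 without TPTN replicate 1, 9 without TPTN replicate 2 and 5 without TPTN replicate 3. It was 10 in fits of only the groups compared and 15 with the replicate block. A test over all 3 groups found 508 genes, of which 496 were marked yes in the authors' deposited table. That mark was held by 2675 of the genes tested. A deposited q-value under 0.05 was held by 431 of the 508 and by 984 of the genes tested.

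Nppa and other atrial genes differed between the DOX libraries. Nppa stood at 1736, 288 and 195 FPKM in DOX replicates 1, 2 and 3, against 94.0, 51.2 and 147 in control and 118, 120 and 52.6 in TPTN. The sum of Myl7, Myl4, Sln and Bmp10, genes of atrial muscle, was 775 FPKM in DOX replicate 1 and 0.142 to 1.16 in the other 8 libraries.

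**Figure D4:**
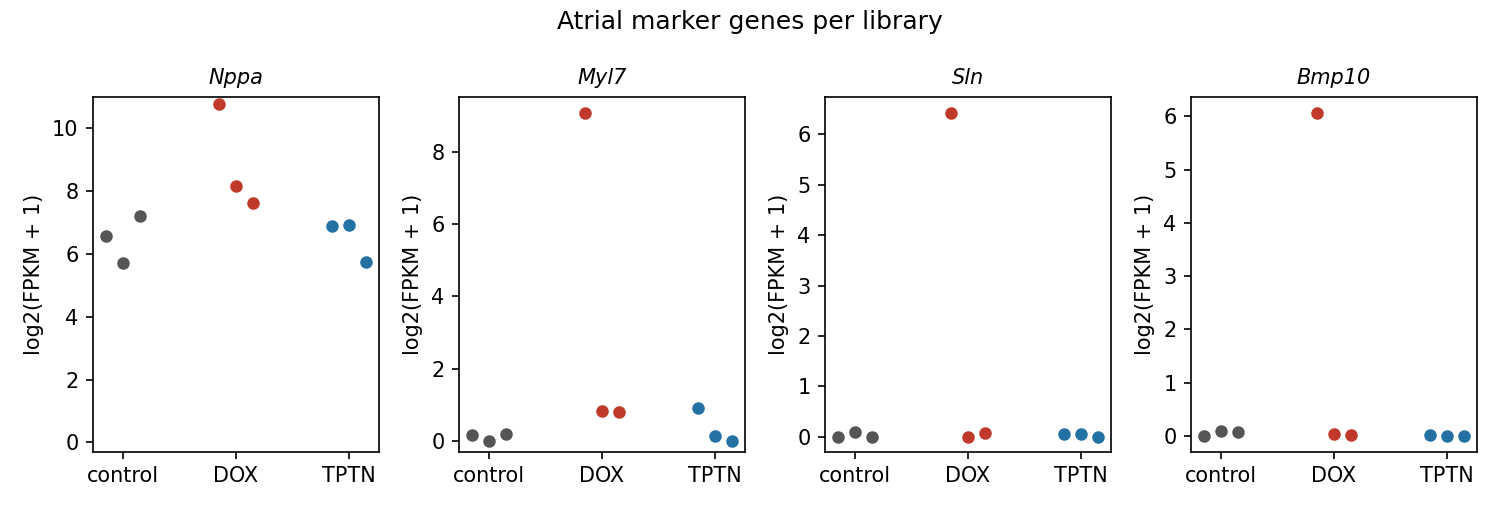
Expression of Nppa, Myl7, Sln and Bmp10 in each library of the control, DOX and TPTN groups, as log2(FPKM + 1) on the vertical axis. DOX replicate 1 lies above the 8 other libraries, with Nppa at 1736 FPKM against 51.2 to 288.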

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

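The scalings, the removal of the trend on length and GC content and the fit without control replicate 3 and TPTN replicate 1 were chosen only after the data were seen. The count-based settings fixed in advance (another count tool, RLE, upper-quartile and library-total scaling, both count filters and voom) were not run, since counts were not used here. Where no cause is given, the cause was not tested.

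Over all alternatives, values of the tallied named genes past the threshold kept direction and side in 1231 cases and lost the threshold in 594. Those of lists, by camera's direction, did so in 605 and 138, and 1 reversed. That was fatty acid oxidation in TPTN against DOX at a median of 0.035 under quantile normalization (camera adjusted p = 0.49). Medians alone also changed sign: without mitochondrial genes and copies in the sum, this list (0.0097) and autophagy (0.011) in TPTN against DOX; in TPTN against control, NRF2 and autophagy without mitochondrial genes alone (0.012 and 0.015) and without control replicate 3 and TPTN replicate 1 together (0.021 and 0.049). With 1 library left out, NRF2, muscle atrophy and autophagy did so in TPTN against control. Values not past the threshold stayed so in 2523 cases for genes and 182 for lists, and 93 and 10 passed. Counts stayed within 1.5 times without robust estimation, with a pseudocount of 0.1 and with a minimum mean of 1 FPKM, apart from small parts of the overlap. Genes that fell in DOX and rose in TPTN numbered 7 without robust estimation, against 11. Genes of the same sign in both comparisons numbered 1 there and with a pseudocount of 0.1, against 3.

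A minimum absolute log2 change of 1 left 3 higher and 2 lower genes in DOX against control, 2 and 4 in TPTN against DOX and 2 and 8 in TPTN against control. An estimated correlation left 0, 0 and 1 lists in the same order, and fry gave 3, 4 and 3. Fitting only the groups compared gave 149 and 27 genes in DOX against control, 68 opposite and 10 same-direction calls. With no filter, more genes of low level were tested, and 2 and 0, 0 and 2, and 1 and 5 genes passed in limma (at an unadjusted p under 0.05, 2085 and 737, 1348 and 1913, and 1441 and 846), with 1 opposite and 0 same-direction calls and 10 lists in DOX against control. Genes with a symbol only gave 88 and 73 genes in TPTN against control, with fewer genes tested.

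Median ratios gave 118 higher genes in DOX against control, 151 in TPTN against DOX and 91 opposite calls. Without mitochondrial genes and their copies in the sum the counts were 61 and 209, and 542 and 129; without mitochondrial genes alone they were 187 and 170 in TPTN against DOX and 90 higher in TPTN against control. Quantile normalization gave 76 higher genes in DOX against control, 173 and 163 in TPTN against DOX, 62 opposite calls and 9 lists in TPTN against control. With the trend on length and GC content removed there were 104 and 23, and 38 and 95 genes, 29 opposite calls and 10 lists in DOX against control. Without control replicate 3 and TPTN replicate 1 together, with fewer samples, 5 and 0, 1 and 5, and 0 and 0 genes passed in limma (at an unadjusted p under 0.05, 1492 and 320, 822 and 1086, and 968 and 350), with 0 opposite and 0 same-direction calls.

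Leaving out 1 library gave 2 to 268 higher and 0 to 57 lower genes in DOX against control, 9 to 162 and 31 to 330 in TPTN against DOX, and 4 to 85 and 14 to 74 in TPTN against control. Opposite calls ranged from 2 to 149, same-direction calls from 0 to 27, and lists from 6 to 10, 8 to 13 and 6 to 15.

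With the replicate number as a block, 141 and 29 genes passed in DOX against control, 37 and 122 in TPTN against DOX and 24 higher in TPTN against control, with 52 opposite and 15 same-direction calls. Deviations of libraries with the same number correlated at -0.26 to 0.02, and not every sample correlated best with its own number, so the numbers were not taken to pair the libraries. Under other numbers, control and TPTN libraries correlated at 0.398 (control 3 with TPTN 1), 0.293 (control 1 with TPTN 2) and 0.226 (control 2 with TPTN 3), a shared structure whose cause was not tested. The estimated depth of 18.3 to 24.3 M read pairs, with FPKM and no counts, limits the precision of genes of low level.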

Other observations

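The tests of ribosomal protein genes against mitochondrial share and ribosomal RNA, of glucocorticoid-responsive genes and of atrial tissue were chosen only after the result was seen; those of length and GC content and of other splits of the samples were set before. The actin gene Actb, Actg1 and the tubulin gene Tuba1b, chosen after their values were seen, were among the 23 that differed from control in the same direction in DOX and TPTN: Actb by 0.62 and 0.72, Actg1 by 0.61 and 0.65 and Tuba1b by 0.66 and 0.60 on the log2 scale. Actb and Actg1 share reads with near-identical copies and are uncertain. Among neutrophil genes, S100a8 averaged 2.25 ± 1.37 FPKM in control, 0.621 ± 0.644 in DOX and 0.0488 ± 0.0845 in TPTN, and S100a9 3.81 ± 1.66, 1.55 ± 0.734 and 0.152 ± 0.101 (SD, n = 3 each).

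Ribosomal protein genes were higher in DOX than in both other groups. With the trend on length and GC content removed, the median of the list in DOX against control was 0.32 against 0.38 uncorrected, and 0.27 at the lowest, without control replicate 2, which argues against that trend as the whole cause. A smaller mitochondrial share raises all other genes alike, but the list lay 0.28 above the 2355 other nuclear genes with a mean of at least 10 FPKM (0.25 at the lowest, without control replicate 2), which argues against that share as the whole cause, while its median when scaled without mitochondrial genes and their copies, tested first, was 0.22, and 0.18 without control replicate 2 against a bound of 0.19, which leaves a part open. Only TPTN replicate 3 had as much RNA related to 18S, at 3668 FPKM, and its ribosomal protein sum of 4849 lay below the DOX libraries (SD 207), which is too few libraries to settle whether ribosomal RNA or RNA quality may play a part. An effect of the doxorubicin model remains open as an untested hypothesis.

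The fall of glucocorticoid-responsive genes in TPTN against control had a median of -0.86 at its nearest to 0 over the 4 other scalings (largest adjusted p = 1.25e-21), which argues against scaling as its cause. S100a8 and S100a9 together lay 5.86 FPKM lower, against a fall of 38.9 FPKM for the 9 called members. The share was 15.1%, and 10.5 to 18% leaving out 1 library, which argues against fewer neutrophils as the source of the summed fall. The sums cover 2 and 9 genes, so they cannot decide this for single members of low level, such as Fkbp5. Of 18 clock genes outside the list, 5 differed adjusted over the list alone, among them Nr1d1 at 1.07 and Bhlhe40 at 0.73, while Arntl, which runs opposite to Nr1d1 over the day, was at -0.02. Another time of day at collection stays open, and lower glucocorticoid signalling in the TPTN group is an untested hypothesis beside it. Bhlhe40 and Arntl were singled out from the clock list after their values were seen, as were S100a8 and S100a9 from the neutrophil list.

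Of 12 atrial markers in the table, 10 were highest in DOX replicate 1. This restates the pattern, so atrial tissue in that library stays open as an untested hypothesis. Nppa in DOX replicates 2 and 3 also lay above the control libraries. There the sum of Myl7, Myl4, Sln and Bmp10 exceeded control by 0.764 FPKM, against 68.1 FPKM that the ratio in replicate 1 would need. If the ratio in replicate 1 is taken as that of atrial tissue, this argues against atrial tissue for those libraries. No other explanation was tested for them.

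Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split gave 329, 407 and 90 genes in DOX against control, TPTN against DOX and TPTN against control, and the highest of the others 6, 2 and 2, so 1 of 10 splits in each gave as many. For lists with the preset correlation the real split gave 6, 11 and 14 and the highest other 14, 14 and 13, with 9, 3 and 1 of 10 splits giving as many. Mixed labels thus gave as many lists in DOX against control and in TPTN against DOX. The number of lists past the threshold does not set the real groups apart there. In 100 splits of the 9 libraries into 3 groups, only the real split gave as many opposite calls (144, highest other 11). The same held for same-direction calls (23, highest other 4) and for genes over the groups (508, highest other 159). Each count was thus reached in 1 of 100 splits, the real one included. The other splits were counted under 1 random labelling of their groups, and opposite and same-direction calls depend on which group is shared. Their highest counts of such calls may thus be understated: the split with 159 genes gave 0 opposite calls under its labelling. Splits that mix the groups call few genes, so they cannot show how many shared calls come from the shared libraries.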
